A study of Triticum aestivum with 6 samples.

How the data were processed

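The deposited data were a table of raw counts per gene identifier with 1 column for each of the 6 libraries. The authors deposited these counts without normalisation, as whole numbers with different totals. HISAT2, a spliced read aligner, is named in the submitters' processing notes without a version. The program that counted reads, the genome build, the annotation, the strand setting and any filter are not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol and checked on a Bioanalyzer, and libraries followed an Illumina protocol. Reads of closely similar copies of a gene in the 3 subgenomes can be shared out in ways the counts do not show, so values of single copies are uncertain. Without a stated strand setting, antisense partners could not be told apart.

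Groups and replicate numbers came from the sample titles. The treatment text and the stage entry were the same in all 6 samples and defined no group. Nothing in the labels says whether the 3 libraries of a group came from separate plots or plants, so p-values measure only the spread between these libraries, which may be technical. Counts of every pair of libraries differed beyond sampling noise, with a chi-square of 4.26 to 18.0 per degree of freedom, so no library was counted as a copy of another. Totals ran from 10561224 to 13088727 counts.

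Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (min.count 10, min.total.count 15), scaled by TMM and compared with the quasi-likelihood test, two-sided and without covariates. The p-values were adjusted by Benjamini and Hochberg over 50136 genes, with 0.05 as the threshold. The biological coefficient of variation was 26.5%. CPM of single genes in the report are scaled by TMM. Sums over gene groups and all CPM in the closing section are CPM scaled by library size alone, without TMM. Standard errors and 95% intervals are on the log2 scale, from the same fit. Principal components were computed on log2 CPM with a prior count of 2. Shares of subgenomes and sums over gene groups were compared with an exact permutation test, for which 3 against 3 libraries give a smallest p of 0.1.

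Identifiers named the chromosome arm for 102154 of the 102602 entries, and 328 were gene symbols, of which 112 were tested. The reference table of IWGSC CS RefSeq v2.1 matched 92 identifiers by symbol or synonym and held no descriptions. The 22 gene lists that had been fixed before the data were examined relied on descriptions and could not be run, as none reached 5 tested members and the largest had 3. In their place 12 groups were assembled from the symbols after the values had been seen. The 10 groups with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 10 groups, and with fry from limma 3.58.1. Sets of genes by chromosome arm were also added after the data were seen. The named genes were based on a rule fixed before the data were examined. As no gene was called, it asked for the 5 lowest unadjusted p-values in each direction. Without joined names, it allowed at most 2 identifiers in each direction. Both parts were used, the first among genes with a symbol and the second among identifiers without one. The fixed rule stated neither their joint use nor these limits. The 5 most abundant genes, from 6216 to 9157 CPM, had no symbol and are not named. Members of the symbol groups are named as examples. A test of called genes across subgenomes had been fixed too and was not run, since there was no called gene.

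Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling and library size alone, no filter and a stricter one (1 CPM in at least 3 libraries), robust estimation, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, a log2 fold limit of 1, leaving out the 100 most abundant genes, and leaving out each library in turn. A fit with CK and SPD replicates 1 and 2 only was added after the data were seen.

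The gene test was tested on simulated data drawn from the means, spread and totals of the real libraries. In these, 200 genes were changed, all with a mean of at least 5 CPM. Of these, it recovered 0% at 1.5-fold with 2 false calls, 33.0% at 2-fold with 8 false calls among 74, and 95.5% at 4-fold with 15 false calls among 206. In a further draw of such data, camera picked out a set of 6 genes raised 2-fold and not a set of 6 unchanged genes. Genes were drawn independently there, so this says nothing about camera at its preset correlation where genes are correlated. No simulated library stood apart from the others as SPD replicate 3 did, so recovery by the gene test in the real libraries may differ too. A search for genes nearly absent from or nearly exclusive to 1 library, used in the closing observations with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, found 50 of 50 removed and 30 of 30 added genes in simulated counts.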

Results

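RNA was sequenced from inferior grains of field-grown bread wheat, Triticum aestivum, of the cultivar Xinong 538. Inferior grains are those that set later within a spike and usually fill less. The sample titles gave 2 groups, SPD and CK, with 3 libraries each. The labels spelled out neither abbreviation, and all 6 libraries carried the same treatment text, which named exogenous spermidine, a polyamine. They also shared one stage entry naming days 8 and 16 post anthesis, so stage could not be separated. The series as a whole concerns spermidine in the filling of inferior grains. Whether SPD against CK is a contrast of treated with untreated grains is not given in the sources used here. Total counts per library were 12496382, 11070027 and 13088727 in CK replicates 1 to 3 and 12236411, 12984627 and 10561224 in SPD replicates 1 to 3. Of 102602 gene identifiers, 72925 had at least 1 count and 50136 passed the filter on low counts.

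SPD replicate 3 stood apart from the other 5 libraries. The first principal component held 35.4% of the variance and placed that library at 140, against -42.6 to -20.7 for the rest. The second component, with 21.3%, placed SPD replicate 1 at -105. CK replicates 1, 2 and 3 and SPD replicate 2 lay between 11.1 and 42.4 on it. The 100 most abundant genes took 19.7% of the counts in SPD replicate 3 and 16.0% to 17.0% in the others.

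**Figure D1:**
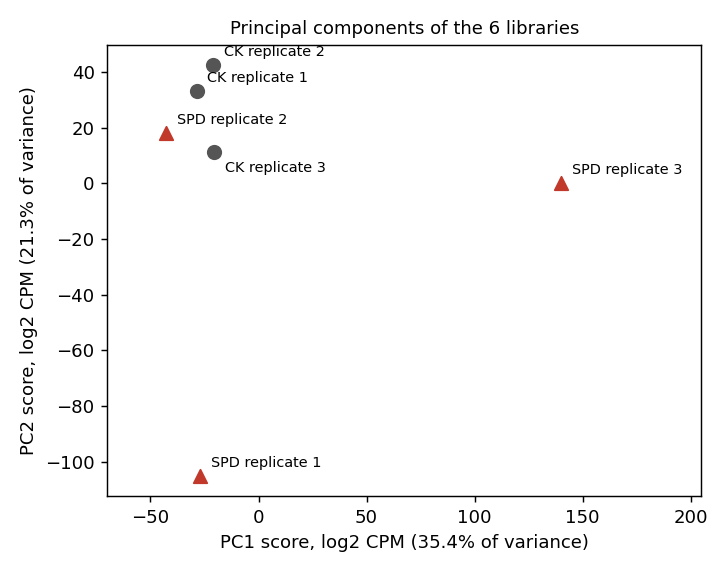
Scores of the 6 libraries on the first and second principal components of log2 CPM, with 35.4% and 21.3% of the variance. Grey circles are CK and red triangles SPD. SPD replicate 3 lies at 140 on the horizontal axis, apart from the other libraries.

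No gene differed between SPD and CK in the grain after adjustment for the number of genes tested. Mean log2 fold changes were 0.019 for starch synthesis genes, 0.015 for storage and grain texture genes, -0.15 for thionins and grain inhibitors and 0.60 for photosynthesis genes. With 1 library left out at a time, the starch synthesis mean ran from -0.059 to 0.059. That of storage and grain texture genes ran from -0.26 without SPD replicate 3 to 0.15 without SPD replicate 1. PORA, a gene of chlorophyll synthesis, had the lowest unadjusted p-value among genes with a symbol, at a log2 fold change of 1.04 (SE 0.34, n = 3 per group). On the lower side, XIPI, a xylanase inhibitor protein, lay at -0.69 (SE 0.31), at -0.34 without CK replicate 2 and at -0.42 without SPD replicate 1. Without SPD replicate 3, PORA lay at 0.61. The quasi-likelihood test of edgeR called 0 genes higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.997. Without adjustment, 1800 genes lay below 0.05, 955 higher and 845 lower, which is 3.59% of those tested where chance gives 2507 genes, or 5%. Without SPD replicate 2 the count was 4033, or 7.76%, and without CK replicate 1 it was 1080, or 2.08%, with 0 genes called in both fits. The Wald test of DESeq2 called 3 genes, all lower in SPD, and limma-voom called 0. The SPD and CK values did not overlap in 4754 genes, or 9.48%, where chance gives 10%. In simulated counts of the same depth and spread the edgeR test recovered 95.5% of the genes changed 4-fold, 33.0% of those changed 2-fold and 0% of those changed 1.5-fold. The changed genes all had a mean of at least 5 CPM, so recovery among genes below that level was not measured. Simulated genes were independent and no simulated library stood apart like SPD replicate 3, so recovery in the real libraries may differ. The median 95% interval of a log2 fold change reached 0.65 to either side of it, and 0.40 in the 18465 genes with a mean of at least 10 CPM.

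The starch synthesis genes with a symbol were AGP-L, AGP-S, AGA.1, WAXY and WSSI-2. AGP-L, AGP-S and AGA.1 encode subunits of ADP-glucose pyrophosphorylase, WAXY the granule-bound starch synthase that makes amylose, and WSSI-2 a soluble starch synthase. None of the 5 was called, and 2 had positive and 3 negative fitted values. WAXY had 2058 ± 41.3 CPM in CK and 1926 ± 201 in SPD (mean ± SD, n = 3), with a log2 fold change of -0.10 (95% interval -0.31 to 0.12). With 1 library left out at a time it ran from -0.18 without SPD replicate 2 to -0.027 without SPD replicate 1. AGP-S had 1815 ± 148 CPM in CK and 1890 ± 86.6 in SPD, at 0.06 (-0.15 to 0.27). These intervals leave out a 2-fold change of either gene. Sums over gene groups were scaled by library size alone, without TMM. Summed over the 5 genes, levels were 5292 ± 204 CPM in CK and 5111 ± 404 in SPD, with a two-sided exact permutation p of 0.7. With 3 libraries against 3 this test cannot give a p below 0.1. BMY1, a beta-amylase, and AMY1.1, an alpha-amylase, act in starch breakdown. BMY1 had 426 ± 3.78 CPM in CK and 511 ± 82.4 in SPD, a log2 fold change of 0.26 (95% interval -0.01 to 0.53). All 3 SPD values lay above all 3 CK values, and without SPD replicate 3 the log2 fold change of BMY1 was 0.13. Scaled by library size alone, unlike the BMY1 values, the sum of BMY1 and AMY1.1 was 426.6 ± 5.67 against 506.7 ± 72.6 CPM (two-sided exact permutation p = 0.1). That difference was not called, and SPD replicate 3 held the highest sum, 583.1 CPM on that scale.

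The storage and grain texture genes were AVNLA, an avenin-like protein, GLU-D1-2B, a high molecular weight glutenin subunit, and the puroindolines PINA and PINB, which set grain hardness. PINA had 3091 ± 58.7 CPM in CK and 3184 ± 447 in SPD, a log2 fold change of 0.04 (95% interval -0.19 to 0.28). PINB had 3626 ± 159 and 3596 ± 319 CPM, at -0.012 (-0.21 to 0.19). AVNLA was more variable, with 3789 ± 322 CPM in CK and 4239 ± 1940 in SPD. Its level in SPD replicate 3 was 6479 CPM, against 3103 and 3134 in the other SPD libraries, and its log2 fold change went from 0.16 to -0.28 without that library. Summed over the 4 genes, the levels were 10480 ± 265 and 10890 ± 2340 CPM (two-sided exact permutation p = 1). The purothionin genes THI1.1 and THI1.2 had log2 fold changes of -0.032 (SE 0.11) and 0.014 (SE 0.11). The sign of PINA, PINB, THI1.1 and THI1.2 changed with the library left out. IMA1, an alpha-amylase inhibitor, lay at -0.12 (SE 0.11), or at -0.018 without SPD replicate 1, and the thionin gene TTHV at 0.09 (SE 0.23), or at -0.25 without SPD replicate 3 and -0.044 without CK replicate 1. With XIPI these 5 genes summed to 9730 ± 84.0 CPM in CK and 9314 ± 1100 in SPD (two-sided exact permutation p = 0.7). XIPI itself had 134 ± 52.4 CPM in CK and 83.1 ± 34.0 in SPD. For starch synthesis the camera test of edgeR gave an adjusted p of 0.939, for storage and texture genes 0.939 and for thionins and inhibitors 0.626. Without SPD replicate 3 the mean log2 fold change of thionins and inhibitors went from -0.15 to -0.28 and the adjusted p of camera, at its preset correlation, to 0.0223. With all 6 libraries the estimated correlation of these genes was 0.553, and the adjusted p with it was 0.885.

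**Figure D2:**
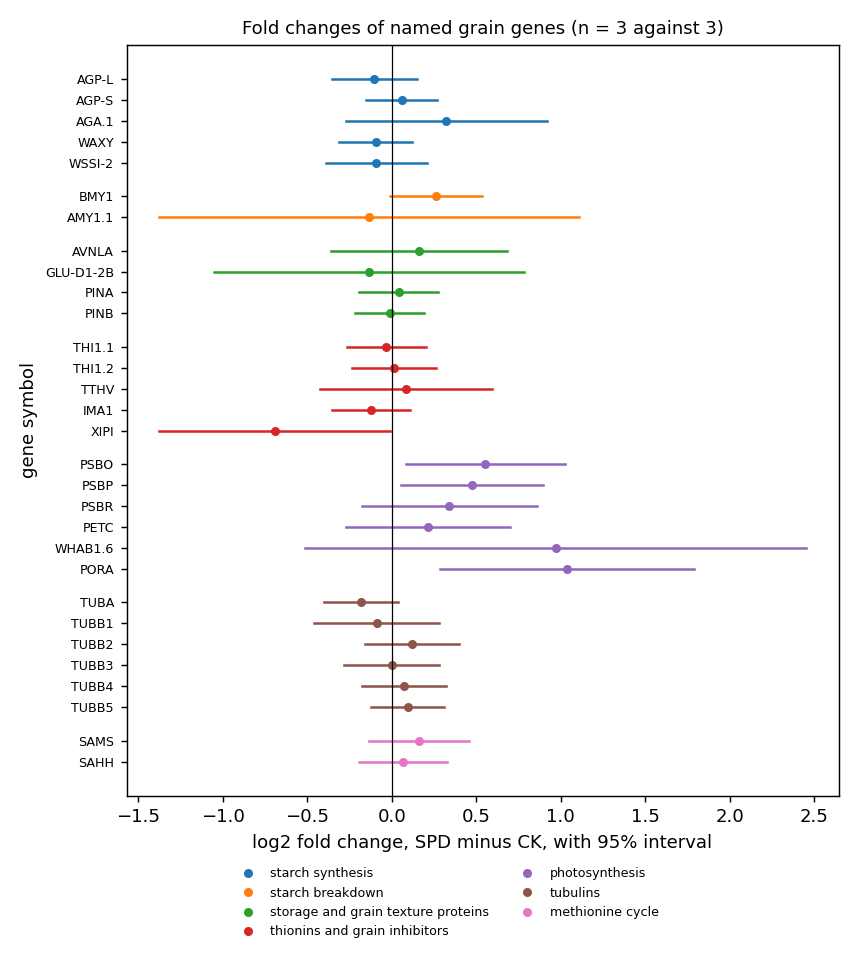
Fitted log2 fold changes, SPD minus CK, of named grain genes by function, with 95% intervals as bars (n = 3 per group). Starch synthesis, storage and tubulin genes lie on both sides of 0, with AGA.1 at 0.32, and the 6 photosynthesis genes all lie above it with all 6 libraries, up to 1.04 for PORA, though PSBR and PETC lie below it without SPD replicate 3. No gene passed adjustment over all genes tested.

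Photosynthesis genes, of which the grain's green pericarp is a known place of expression, were the one group past the test against other genes. All 6 members had positive fitted values with a mean log2 fold change of 0.60, and camera gave an adjusted p of 0.00027 over the 10 groups. The groups were assembled after the values had been seen, so this is not an independent test. This group holds PORA, PSBO and PSBP, which had the lowest unadjusted p-values of edgeR on the higher side among genes with a symbol. With an estimated correlation between the genes the adjusted p was 0.885, and the correlation itself was 0.916. PORA, a protochlorophyllide oxidoreductase of chlorophyll synthesis, had 16.7 ± 4.77 CPM in CK and 34.3 ± 17.4 in SPD. PSBO and PSBP, proteins of the oxygen-evolving complex of photosystem II, had log2 fold changes of 0.55 (SE 0.21) and 0.47 (SE 0.19). PSBR, also of photosystem II, lay at 0.34 (SE 0.23). PETC, the Rieske protein of the cytochrome b6f complex, lay at 0.22 (SE 0.22), and WHAB1.6, a chlorophyll a/b-binding protein with few counts, at 0.97 (SE 0.67). None of the 6 was called, also when adjusted over the group alone. The summed level, scaled by library size alone, was 448.7, 552.2 and 429.2 CPM in CK replicates 1 to 3 and 624.4, 438.4 and 876.5 CPM in SPD replicates 1 to 3 (two-sided exact permutation p = 0.3). The highest value belonged to SPD replicate 3, and SPD replicate 2 lay within the range of CK. Without SPD replicate 3 the mean log2 fold change was 0.20 and the adjusted p of camera 0.183. The values without it were 0.61 for PORA, 0.29 for PSBO, 0.24 for PSBP and 0.10 for WHAB1.6, and those of PSBR and PETC were negative, at -0.015 and -0.044.

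**Figure D3:**
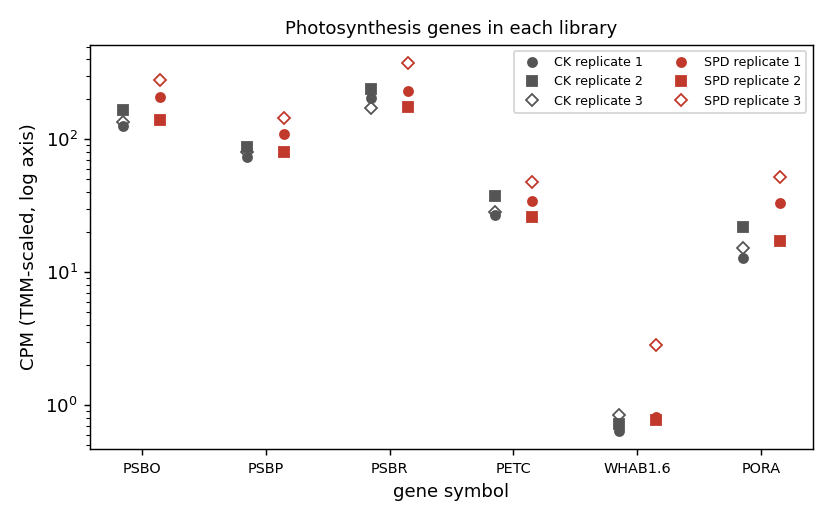
TMM-scaled CPM, on a log axis, of 6 photosynthesis genes in each library. Grey symbols are CK and red symbols SPD, with the replicate given by the shape. SPD replicate 3, the open red diamond, has the highest value for each gene, such as 52.1 CPM for PORA.

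The other gene groups did not pass the test. The 3 small heat shock protein genes, HSP16.9A, HSP16.9B and HSP21, all had negative fitted values with a mean log2 fold change of -0.54 (camera, adjusted p = 0.0913, and 0.885 with an estimated correlation). HSP16.9A, with 0 to 33 counts per library, lay at -0.73 (SE 0.86), and HSP21, with 9 to 73, at -0.66 (SE 0.61). HSP16.9B, with a mean of 70.6 CPM, lay at -0.24 (SE 0.23). Sums over the 3 genes, again on library size alone, were 87.2, 85.6 and 73.4 CPM in CK and 53.5, 103 and 46.8 CPM in SPD (two-sided exact permutation p = 0.4). Without SPD replicate 2, the library with the highest sum, the mean was -1.48 and the adjusted p 1.63e-05, and without CK replicate 3 they were -0.74 and 0.0429. Without SPD replicate 3 they were -0.17 and 0.755, without CK replicate 1 they were -0.31 and 0.447, without SPD replicate 1 they were -0.35 and 0.462, and without CK replicate 2 they were -0.55 and 0.207. These values and that with the replicate number as a block, -0.855 with an adjusted p of 0.0119, were at the preset correlation. TUBA, an alpha-tubulin, had 2580 ± 76.2 CPM in CK and 2275 ± 252 in SPD, with a log2 fold change of -0.18 (SE 0.10). All 3 SPD values of TUBA lay below those of CK, the lowest being 1986 CPM in SPD replicate 3, without which the log2 fold change was -0.09. The 5 beta-tubulins TUBB1 to TUBB5 brought the mean of the tubulins to 0.0029, and to -0.0041 with library size as the only scaling (adjusted p = 0.939 and 0.966). Summed on library size alone, the 6 tubulins had 3367 ± 91.5 CPM in CK and 3083 ± 308 in SPD (two-sided exact permutation p = 0.2). The lowest sum, 2736 CPM, belonged to SPD replicate 3. PER1, a peroxiredoxin of seeds, had 141 ± 16.4 CPM in CK and 110 ± 14.4 in SPD, at -0.36 (SE 0.14). It was 1 of the 6 genes for antioxidant enzymes, which had a mean of -0.03 (adjusted p = 0.799). That mean was 0.097 without SPD replicate 2 and -0.15 without SPD replicate 3. TH123, a histone gene, lay at -0.33 (SE 0.25), or at -0.07 without SPD replicate 3, and the 6 histone genes had a mean of -0.08 (adjusted p = 0.799). UBA1, a ubiquitin-activating enzyme, lay at -0.22 (SE 0.13), or at -0.12 without SPD replicate 3. The mean over 5 genes of ubiquitin activation and conjugation was 0.03 (adjusted p = 0.874), with 1 positive and 4 negative values. Summed on library size alone, these 5 genes had 388.1 ± 6.63 CPM in CK and 362.2 ± 20.6 in SPD (two-sided exact permutation p = 0.1). The lowest sum, 338.5 CPM, belonged to SPD replicate 3. The 3 tested genes of gibberellin synthesis and response had a mean of 0.34 with 1 positive and 2 negative values (adjusted p = 0.799). Medians had another sign than these means for starch synthesis (-0.09), antioxidant enzymes (0.0045), gibberellin (-0.05) and ubiquitin genes (-0.039), and the camera test pointed down for starch synthesis and ubiquitin genes. SAMS and SAHH, S-adenosylmethionine synthetase and S-adenosylhomocysteine hydrolase, belong to the methionine cycle, which also feeds spermidine synthesis. Their sum was 221.4 ± 11.9 CPM in CK and 235.7 ± 17.8 in SPD (two-sided exact permutation p = 0.6).

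The 2 further named genes with positive fitted values were WZCI, at 0.48 (SE 0.20), and MIR1122, a microRNA precursor, at 0.37 (SE 0.16). WZCI had 2572 ± 380 CPM in CK and 3596 ± 1266 in SPD, with 5056 CPM in SPD replicate 3, without which its log2 fold change was 0.16. Among identifiers without a symbol, Traes_7DL_FB75EA9C3 had 84.3 ± 14.0 CPM in CK and 46.9 ± 1.34 in SPD, a log2 fold change of -0.84 (SE 0.14). Traes_7BL_992E1F443 had 83.3 ± 2.78 and 50.9 ± 5.31 CPM, at -0.71 (SE 0.12). Both had an adjusted p of 0.997 in edgeR, and the Wald test of DESeq2 gave them adjusted p values of 0.00924 and 0.0213. The gene that DESeq2 called besides these, Traes_1AL_F4F1F73DF, had 28.5 ± 7.41 CPM in CK and 11.4 ± 3.88 in SPD, and was singled out after its values were seen. On the other side, Traes_2BL_C80835336 had 15.2 ± 0.92 and 26.7 ± 3.45 CPM, at 0.81 (SE 0.16). Traes_6AL_D2CA55216 had 1.30 ± 0.42 and 4.67 ± 1.45 CPM, at 1.84 (SE 0.41). Both had an adjusted p of 0.997 in edgeR.

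Wheat carries the subgenomes A, B and D, and their shares of the counts differed between the groups by less than 1 SD of the SPD libraries. Genes of A took 32.2% ± 0.11 of the counts in CK and 32.3% ± 0.35 in SPD, those of B 29.95% ± 0.16 and 29.7% ± 0.27, and those of D 33.8% ± 0.069 and 33.9% ± 0.19. The two-sided exact permutation p was 1 for A, 0.3 for B and 0.4 for D. None of the 41 chromosome arms stood apart from the others in fold change, with a smallest adjusted p of 0.995 in camera and 0.979 with an estimated correlation.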

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

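The gene groups and all their alternatives, and the fit with replicates 1 and 2 only, were chosen after seeing the data. The count of called genes was 0 under 3 other scalings, both other filters, robust estimation, a log2 fold limit of 1, limma-voom and without the 100 most abundant genes. The Wald test of DESeq2 called 3 genes, all lower in SPD (1895 at an unadjusted p under 0.05). With 1 library left out at a time, the count ran from 0 to 1. The 1 was Traes_7BL_05860C94A, lower in SPD without CK replicate 3. Over all libraries of each group, the left-out CK replicate 3 included, it had 8.41 ± 7.4 CPM in CK and 0.0272 ± 0.0472 in SPD. It was called as the 1 gene with replicates 1 and 2 only, too, and did not pass the filter with all 6 libraries. The number below an unadjusted 0.05 ran from 1080 (2.08%) without CK replicate 1 to 4033 (7.76%) without SPD replicate 2, and was 2515 (4.84%) without SPD replicate 3 and 2761 (5.45%) with replicates 1 and 2 only, where chance gives 5%.

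Samples with the same replicate number did not deviate together (correlations of 0.016, -0.058 and -0.029), and the libraries of number 1 alone correlated best with their own number. With the number as a block, 0 genes were called, 1445 lay below an unadjusted 0.05, and the small heat shock protein genes had a mean log2 fold change of -0.855 with an adjusted p of 0.0119 at the preset correlation of camera. Without the block, the estimated correlation of these genes was 0.864 and the adjusted p with it 0.885. The block changed no other call.

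Of 130 alternative values of the 10 groups, 121 stayed on their side of the threshold. For photosynthesis the mean log2 fold change ran from 0.20 to 0.84 with 1 library left out, the lowest without SPD replicate 3, and was 0.16 with replicates 1 and 2 only (adjusted p = 0.455). At 0.60 the call was lost with an estimated correlation (adjusted p = 0.885). The fry test, which asks whether the genes move, on balance, one way and not whether they differ from other genes, gave 0.827 at 0.60. Adjusted p values over all its alternatives ran from 8.96e-09 to 0.885. For thionins and grain inhibitors the mean ran from -0.28 to -0.0023 with 1 library left out, and was -0.31 with replicates 1 and 2 only (adjusted p = 0.0351, at the preset correlation). With all 6 libraries and an estimated correlation, 0.553, the adjusted p of this group was 0.885. For small heat shock proteins it ran from -1.48 to -0.17. The cause was not tested. The 59 named genes had 988 alternative values, of which 2 had an adjusted p under 0.05, both with DESeq2, and 62, in 27 genes, had the other sign. The 22 fixed lists and the subgenome test of called genes were not run under any alternative. In simulated counts of the same depth and spread, the gene test recovered 33.0% of the changes of 2-fold. That share holds for genes with a mean of at least 5 CPM, where all changes were simulated. Genes were drawn independently there, with no library set apart like SPD replicate 3, so recovery in the real libraries may differ.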

Other observations

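The edgeR test of SPD against CK was planned, and the other tests in this part were chosen after the result was seen. CYS1, a cysteine synthase gene, had 964, 906 and 1013 counts in CK replicates 1 to 3 and 1025 and 1087 in SPD replicates 1 and 2, but 55 in SPD replicate 3. It was the 1 gene with a symbol among 191 that set this library apart. In that set, 107 genes had at least 5 CPM in each other library and lay over 8-fold below the lowest of these in SPD replicate 3. The other 84 had at least 5 CPM there and lay over 8-fold lower in every other library. The same search gave at most 1 gene in each of the other 5 libraries.

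The edgeR test called 0 genes in the real grouping, and the highest of the other groupings of the 6 libraries called 1. With a real count of 0, all 10 splits gave as many by construction, so this count says nothing about chance, and 10 splits are also too few for a share under 0.05. Without adjustment, 1800 genes lay below 0.05 in the real split and 3652 in the highest of the others. Of the 10 splits, 6 had at least as many as the real one, which is itself counted among the 6.

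Shallower sequencing is argued against as the source of the genes that set SPD replicate 3 apart. After all libraries were thinned to 10561224 counts, 190 such genes remained in it and at most 1 in any other library. Among the genes lower there, 65 were at least 32-fold lower than in the lowest other library, against 13 that were 16- to 32-fold lower. The share of genes that were nearly absent or nearly exclusive ran from 0% on 1DL to 2.53% on 3DS. It differed between chromosome arms (permutation p = 0.0001, the smallest that 10000 permutations can give). The permutation shuffled single identifiers as if independent, so identifiers of an arm that are lost or gained together could lower this p. Grains of another genotype in SPD replicate 3, through seed mixture or a mislabelled sample, are a candidate explanation that the 65 genes and the uneven arms go with. Another developmental stage stays open. Of the 65 genes, 63.1% were at 0 counts, which neither excludes another stage nor asks for it. The class of at least 32-fold took in every gene at 0 counts, so cut-off and depth partly set this share and the 65.

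CK replicate 3 carried low levels of transcripts of SPD replicate 3. Chosen without CK replicate 3, 64 transcripts had a level at least 50 times that in the 4 remaining libraries. Their pooled level in CK replicate 3 was 9.79% of that in SPD replicate 3 (95% bootstrap interval 8.32 to 14.7). The median over single transcripts was 7.78% (quartiles 4.88 to 11.5). The interval came from resampling transcripts, not libraries. When each of those 4 was likewise left out of the choice in turn, which gave 66 to 70 transcripts, its own level was 0.47% to 0.597% and that of CK replicate 3 was 9.74% to 9.84%. Exchange of reads in both directions at that rate would leave no transcript common to the other libraries far below that percentage in SPD replicate 3. Yet 63 transcripts of at least 5 CPM in those 4 libraries lay at least 50 times lower in SPD replicate 3. Of these, 44 were at 0 counts there. The 63 were chosen for that low level, so their pooled level of 0.328% follows from the choice, and only their existence bears on exchange. Reads of the SPD replicate 3 library itself counted in CK replicate 3 would give each transcript the same percentage. But 34.4% of the 64 transcripts lay outside the 95% counting error of the pooled level, against 3.12% in simulated reads with 1 share. In the choices of 66 to 70 transcripts, 33.3% to 37.9% lay outside it. For each of these choices, 200 draws that added the own expression of the library left out gave at most 13.6%. Own expression in CK replicate 3 beyond such levels was not modelled. RNA of the SPD replicate 3 sample itself, mixed in before library preparation, would also give each transcript the same percentage. The uneven percentages bear on it as they do on such reads, and cannot separate it from them. Some other grains of the kind in SPD replicate 3, or RNA from such grains, may have been part of CK replicate 3. No genotype data were analysed here to test this further.

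Few genes of chromosome arm 1BS were detected in any library. On average 16.3% of its 1445 identifiers reached 1 CPM (15.6% to 17.2% per library). The share was 28.9% on chromosome 3B, whose identifiers name no arm, and 43.1% to 54.3% on the other 39 arms. The detected identifiers of 1BS had a median of 3.37 CPM (95% bootstrap interval 2.70 to 4.09), below the 4.82 to 8.05 CPM of those 39 arms. This median does not decide whether 1BS has surplus identifiers that are not genes, since stray reads on such identifiers could lower it too. Arm 1BS may be missing or replaced in Xinong 538, as in wheats that carry an arm of rye in its place, with the remaining reads coming from similar genes elsewhere. Rye sequences were not analysed here, and no group of the design bears on this.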
